A study of Homo sapiens with 26 samples.

How the data were processed

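Gene expression was measured by RNA sequencing in 26 libraries of Jurkat clone E6-1, an established human T cell leukaemia line grown in suspension. Per the labels' protocols, cells were held with excess thymidine, which stalls DNA synthesis, and were then released into medium with cytidine. Each released culture was divided between flasks, and a single dose of 200 µM glycine chloramine (GlyCl, an oxidant made from glycine and hypochlorous acid) or saline was added straight after release. Cells were taken 4, 24, 48 and 72 h after release, spun slowly to leave late apoptotic and dead cells behind, and total RNA was sequenced by a service provider with a protocol for long non-coding RNA. Which RNA was removed or selected before library construction, and whether the libraries kept strand, are not given in the sources used here.

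The deposited table holds whole-number counts per gene and library that are not normalized. Per the submitters' processing notes, cutadapt, BWA 0.7.12, STAR, R 4.0.3, edgeR 3.32.1, DESeq2 1.30.1 and the genome build GRCh38.p12 were used. Which of these made the counts, the counting program, the annotation and any filter on reads or genes are not given in the sources used here. Groups, times and replicate numbers were taken from the labels, and columns were matched to libraries by name. The table has 2 other columns of per-sample values whose names match none of these libraries, and they were not used. The table holds 25249 gene identifiers with version numbers, and all 25249 matched GENCODE release 29, from which symbols, classes and positions on GRCh38 were taken. Without a stated strand setting, reads from a gene and an overlapping or antisense gene cannot be told apart. Near-identical copies share reads in an unknown way: HIST2H2AA3 and HIST2H2AA4 differed by 0.165 % of their summed counts and HIST2H3A and HIST2H3C by 0.208 %, so single histone genes and the SSX2 and SSX2B pair are uncertain as individual genes.

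Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passing filterByExpr over the 8 groups were kept, which left 23346 genes and removed 1903. Libraries were scaled with TMM factors, all 8 groups were fitted in one model so that the groups with 2 libraries could borrow the spread of the others, and each contrast was tested with the quasi-likelihood F test in its robust form. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, and a gene was called at an adjusted p under 0.05. Expression levels are given as CPM, the edgeR counts scaled to a common library size with the TMM factors. The contrasts were GlyCl against control at each of 4 times, the change of that effect from 4 h to each later time, and control at each later time against control at 4 h. The comparisons, tests, gene lists, naming rule and most alternatives were chosen before the data were examined.

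In all, 29 gene lists were tested for NRF2 targets, heat shock chaperones, ATF4 targets, endoplasmic reticulum chaperones, metallothioneins, p53 response genes, G1/S genes, G2/M genes, replication-dependent histones, DNA methylation and methyl donor genes, thiol redox systems, immediate early genes, NF-kappaB targets, T cell identity, T cell activation, apoptosis, cholesterol and lipid synthesis, glycolysis and hypoxia, interferon-stimulated genes, cancer-testis genes, imprinted genes, ribosomal proteins, ribosome biogenesis, the mitochondrial genome, oxidative phosphorylation, the proteasome, B cell and myeloid markers, epithelial, fibroblast and endothelial markers, and nuclear and non-polyadenylated RNA as a sign of RNA quality. Each list was set against all other tested genes with camera in limma 3.58.1, at a preset correlation of 0.01, on log2 CPM with a prior count of 2. The other genes include long non-coding genes and pseudogenes, so a shift between gene classes also moves a list of protein-coding genes in this test. Lists needed at least 5 tested members. Camera was repeated with the correlation estimated from the data.

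Named genes follow a rule. For each GlyCl and each control time comparison it takes the 8 genes of largest log2 fold change in each direction, among called genes with a mean CPM of at least 1, no overlap between the libraries of both groups and a name that is not clone-based. For the changes of effect it takes 4 in each direction. From each list it takes up to 4 called members with the smallest p. DNMT1, HSPA1A, CDKN1A, MT2A, MSRB1 and TXNRD1 are always included, and HMOX1 was not analysed here. In all, 190 gene and comparison pairs, over 127 genes, were examined under each alternative that applies to them and gives a value, and the text names part of them. Groups of 3 against 3 libraries do not overlap for 10 % of genes by chance, and groups of 4 against 4 for 2.86 %.

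Control and GlyCl flasks of one number were taken to come from one synchronised culture, per the labels' protocols, so the numbers pair the libraries. The correlation across genes of the deviations of same-numbered control and GlyCl libraries from their group means was 0.21, 0.248 and 0.185 at 4 h, 0.0401, 0.0697, 0.0484 and 0.0836 at 24 h, 0.0263 and 0.0775 at 48 h, and 0.0961 and 0.102 at 72 h. Differently numbered libraries had −0.142 to −0.0592 at 4 h, −0.115 to 0.087 at 24 h, −0.0775 to 0.0747 at 48 h and −0.102 to 0.0317 at 72 h. Same-numbered values stood above all of these at 4 and 72 h, but not at 24 or 48 h. With only 2 GlyCl libraries, at 48 and 72 h, the 2 values of each control are equal and opposite. The model without the pairing was the main one and the replicate number as a block was an alternative. The labels call the libraries biological replicates and do not state whether they came from cultures started separately, so p-values measure the spread between these samples, which may be partly technical. No pair of libraries of the same group was alike within sampling noise, and pairs across groups were not compared.

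Library totals ranged from 19093747 to 30367791 counts. On simulated counts built from these libraries with 50 genes changed by each fold, 84 % of 2-fold changes were recovered at 4 h (21870 genes run), 78 % at 24 h (21833 genes), 76 % at 48 h (21877 genes) and 80 % at 72 h (21873 genes). Recovery of 1.5-fold changes was 56, 48, 32 and 24 % in the same order, so smaller changes were often not detectable with 2 treated libraries. The changed genes were drawn from those with a mean CPM of at least 1, so recovery of weaker genes is not covered. False calls were 3.98, 5.81, 3.23 and 5.13 % of the calls. In a simulation of the 24 h comparison, camera recovered 10 of 10 shifted lists and called 1 of 19 others. Every member of a shifted list was raised 2-fold, so smaller shifts of lists are not covered. Simulated genes were drawn independently and the libraries of a group alike. False calls from list members that move together, or from a single deviating library, are therefore not covered.

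Alternatives were DESeq2 size factors, no filter on low counts, a CPM of at least 1 in at least 4 libraries, the non-robust fit, limma-voom, the DESeq2 1.42.0 Wald test, a fit of only the groups compared, the replicate block, only the replicate numbers present in both arms, camera with an estimated correlation, fry, and leaving out each library in turn. Library totals without a scaling factor, a fit without both GlyCl 48 h libraries, and list tests with single libraries left out or with library totals were added after the data had been seen.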

Results

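The data are gene counts from 26 libraries of Jurkat cells, in 8 groups of treatment and time. The control groups had 3 libraries at 4 h and 4 at each of 24, 48 and 72 h after release from the thymidine block. The GlyCl groups had 3 libraries at 4 h, 4 at 24 h and 2 at each of 48 and 72 h. Library totals ranged from 23051482 to 30367791 counts in controls and from 19093747 to 28689535 counts with GlyCl. The design asks how a single exposure to GlyCl changes gene expression over 72 h. Component 1 of a principal component analysis held 33.1 % of the variance and component 2 held 14.2 %.

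At 4 h, HIST3H3, a histone H3 gene best known from testis, stood at 89.1 ± 2.3 CPM (SD, n = 3) with GlyCl and at 17.7 ± 3.98 CPM (SD, n = 3) in controls. The gene lies on chromosome 1 from 228424845 to 228425325 (minus strand, GRCh38). Its log2 fold change of 2.33 (SE 0.23, adjusted p = 1.5e-06) was among the largest increases. The muscle kinase gene ALPK3 rose by 2.39 (SE 0.35, adjusted p = 4.33e-05) and IL12RB2, a chain of the interleukin-12 receptor, by 1.97 (SE 0.34, adjusted p = 0.000275). The zinc exporter SLC30A1 rose from 67.5 ± 4.87 to 145 ± 10.5 CPM (SD, n = 3 each, adjusted p = 4.99e-05). The chaperone HSPA8 fell from 480 ± 113 to 194 ± 44.7 CPM (SD, n = 3 each, adjusted p = 4.05e-05), a log2 fold change of −1.31 (SE 0.19). CD248, a surface glycoprotein, fell by 1.52 on the log2 scale (SE 0.23, adjusted p = 5.97e-05). For each of these genes all 3 GlyCl libraries lay on the same side of all 3 controls, which the naming rule requires of the largest changes.

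T cell identity genes moved down together at 4 h. Of 30 tested, 18 fell, 0 rose and 12 were not called (23 lower and 0 higher adjusted over the list alone). Their median log2 fold change was −0.56 (camera adjusted p = 5.46e-12, and adjusted p = 0.481 with an estimated correlation). The adhesion receptor CD2 fell by 1.2 on the log2 scale (SE 0.18, adjusted p = 0.000137) and the costimulatory receptor CD28 by 0.83 (SE 0.13, adjusted p = 6.17e-05). The transcription factors TAL1 (−0.81, SE 0.13, adjusted p = 9.89e-05) and RUNX1 (−0.62, SE 0.1, adjusted p = 0.000135) were lower as well. Immediate early genes, which cells switch on within minutes of a stimulus, moved up. Of 27, 7 rose, 0 fell and 20 were not called (10 higher and 1 lower adjusted over the list alone). The median was 0.37 (camera adjusted p = 9.94e-05, and adjusted p = 0.504 with an estimated correlation). FOS rose from 8.94 ± 2 to 23 ± 3.57 CPM (SD, n = 3 each, adjusted p = 0.00297). The related FOSB rose by 1.33 (SE 0.3, adjusted p = 0.00652) and the phosphatase gene DUSP1 by 0.8 (SE 0.15, adjusted p = 0.000692). Of 18 heat shock chaperone genes 9 fell and 0 rose (11 lower and 0 higher adjusted over the list alone), with a median of −0.54. That list passed the test (camera adjusted p = 0.000104, and adjusted p = 0.504 with an estimated correlation).

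Genes of protein and energy metabolism were also lower at 4 h by the list test, which sets a list against all other tested genes. At 4 h the median log2 fold change was −0.14 for protein-coding genes, with 1995 of 14252 called lower. It was 0.32 for long non-coding genes and 0.32 for pseudogenes. Lists of protein-coding genes thus leaned downwards in this test. Of 36 oxidative phosphorylation genes 10 fell (22 adjusted over the list alone, camera adjusted p = 1.74e-07), and of 32 proteasome genes 8 fell (14 adjusted over the list alone, camera adjusted p = 1.13e-06). Ribosome biogenesis had 6 of 29 genes lower (12 adjusted over the list alone, camera adjusted p = 6.09e-05) and ribosomal proteins 1 of 75 (0 adjusted over the list alone, camera adjusted p = 9.67e-07). None of these lists had a member called higher, and each had an adjusted p = 0.504 with an estimated correlation. The proteasome subunit PSMB5 fell by 0.74 on the log2 scale (SE 0.13, adjusted p = 0.000441) and the nucleolar protein NOP56 by 0.65 (SE 0.15, adjusted p = 0.00476). Of 21 DNA methylation and methyl donor genes 6 fell and 0 rose (6 and 0 adjusted over the list alone). Their median was −0.24 (camera adjusted p = 0.00064, and adjusted p = 0.481 with an estimated correlation). The methyl-CpG binding protein ZBTB33 fell by 0.82 on the log2 scale (SE 0.11, adjusted p = 1.58e-05). The DNA repair glycosylases TDG (−0.65, SE 0.12, adjusted p = 0.000573) and MBD4 (−0.57, SE 0.09, adjusted p = 0.000107) were lower too. DNMT1, the maintenance methyltransferase, was not called (248 ± 27.8 against 256 ± 16.4 CPM, SD, n = 3 each, adjusted p = 0.856).

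Further lists passed the test downwards at 4 h. Thiol redox genes had 8 lower and 0 higher (11 and 2 adjusted over the list alone, camera adjusted p = 0.00585, and adjusted p = 0.504 with an estimated correlation). Replication genes of G1/S had 6 lower and 1 higher (9 and 1 adjusted over the list alone, camera adjusted p = 0.00585). That call had an adjusted p = 0.578 with an estimated correlation and was lost under library totals (0.0646). FEN1, which trims DNA flaps, fell by 0.82 on the log2 scale (SE 0.15, adjusted p = 0.000406). Interferon-stimulated genes had 5 lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.0113). Without control 4 h replicate 2 this was 0.0871, and it had an adjusted p = 0.504 with an estimated correlation. Endoplasmic reticulum chaperones had 4 lower and 1 higher (8 and 1 adjusted over the list alone, camera adjusted p = 0.0137). Without GlyCl 4 h replicate 1 this was 0.0843, and it had an adjusted p = 0.504 with an estimated correlation. The G2/M list passed with 0 of 37 members called, also adjusted over the list alone (camera adjusted p = 0.0135, and adjusted p = 0.702 with an estimated correlation). Its median was −0.19, against −0.14 for all protein-coding genes, and 0.02 under library totals. The G2/M call was lost without control 4 h replicate 1 (adjusted p = 0.0581), without GlyCl 4 h replicate 3 (0.0604) and under library totals (0.0656).

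Of the other lists, NRF2, ATF4 and p53 targets and histones were not called at 4 h. NRF2 targets had 0 higher and 3 lower of 15 (0 and 3 adjusted over the list alone, adjusted p = 0.385). ATF4 targets had 1 higher of 24 (1 adjusted over the list alone, adjusted p = 0.103). The p53 response had 3 higher and 1 lower of 23 (5 and 1 adjusted over the list alone, adjusted p = 0.337), and histone genes had 0 of 55 called (0 adjusted over the list alone, adjusted p = 0.0928). Under library totals the medians of the NRF2 (−0.07), p53 (−0.01) and histone (−0.19) lists were 0.14, 0.21 and 0.02. Under them ATF4 targets had 5 higher and 0 lower (median 0.28 in place of 0.07), the p53 list 6 and 0, and NRF2 targets 0 and 0. The p53 list had a mean of 0.11 and a test leaning upwards, which passed under library totals (0.0453). ATF4 targets passed without GlyCl 4 h replicate 1 (adjusted p = 0.0212) or control 4 h replicate 2 (0.0331). Histones passed downwards without GlyCl 4 h replicate 1 (0.037), control 4 h replicate 2 (0.0108) or control 4 h replicate 3 (0.00775). Single members did rise, namely PPP1R15A, a regulator of eIF2α dephosphorylation (0.66, SE 0.16, adjusted p = 0.00798), and GADD45B (1.16, SE 0.21, adjusted p = 0.000899). CDKN1A (0.36, SE 0.22, adjusted p = 0.295), MT2A (−0.08, SE 0.28, adjusted p = 0.886) and TXNRD1 (−0.04, SE 0.14, adjusted p = 0.898) were not called. HSPA1A was not called either, at 0.483 ± 0.136 against 0.965 ± 0.149 CPM (SD, n = 3 each, adjusted p = 0.262). MSRB1 was not called (−0.32, SE 0.14, adjusted p = 0.115), but was without GlyCl 4 h replicate 2 (−0.46, adjusted p = 0.0442).

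In all, 2832 of 23346 genes were called at 4 h (12.1 %), 715 higher and 2117 lower, of which 384 and 88 changed at least 2-fold. Library totals move the median log2 fold change of all genes from −0.02 to 0.19, and under them 1837 genes were called, 1410 higher and 427 lower. A fit of only the 4 h groups called 968 higher and 1029 lower. By list, library totals left 10 T cell identity, 3 DNA methylation, 2 proteasome, 1 heat shock, 1 ribosome biogenesis and 1 G1/S gene called lower. They left 0 lower for oxidative phosphorylation, thiol redox systems, interferon response and endoplasmic reticulum chaperones, with 0, 1, 1 and 2 higher, and 2 G1/S, 1 DNA methylation and 12 immediate early genes higher. Long non-coding genes were called higher more often than lower (209 against 71) and protein-coding genes lower more often than higher (1995 against 374). The share of counts in non-coding genes was 1.87 ± 0.274 % with GlyCl and 1.4 ± 0.0534 % in controls (SD, n = 3 each). The RNA quality list had 1 of 11 members higher (1 adjusted over the list alone, adjusted p = 0.0606, and 0.0483 with the replicate block). It also passed without control 4 h replicate 1 (0.0149), GlyCl 4 h replicate 2 (0.0363) or GlyCl 4 h replicate 3 (0.0146). The count of called genes fell to 801 without GlyCl 4 h replicate 1, 1417 without control 4 h replicate 2 and 1439 without control 4 h replicate 3.

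At 24 h the replication programme was low in treated cells. Of 31 G1/S and DNA replication genes 30 fell, 0 rose and 1 was not called (30 and 0 adjusted over the list alone). The median was −1.3 (camera adjusted p = 7.12e-28, and adjusted p = 0.0641 with an estimated correlation). The replicative helicase subunit MCM7 stood at 229 ± 46 CPM against 903 ± 22.4 CPM in controls (SD, n = 4 each, adjusted p = 2.52e-13). Its cofactor CDC45 fell by 1.91 on the log2 scale (SE 0.11, adjusted p = 3.49e-14) and the ribonucleotide reductase subunit RRM2 by 1.84 (SE 0.12, adjusted p = 1.28e-13). Of 55 replication-dependent histone genes, which are expressed as DNA is copied, 48 fell, 4 rose and 3 were not called (49 and 4 adjusted over the list alone). Their median was −1.95 (camera adjusted p = 1.13e-33, and adjusted p = 0.0938 with an estimated correlation). HIST1H2BF fell from 1720 ± 179 to 312 ± 60.6 CPM (SD, n = 4 each, adjusted p = 2.06e-13). Histone genes held 2.75 ± 0.718 % of counts with GlyCl against 7.65 ± 0.53 % in controls (SD, n = 4 each). G2/M genes went both ways, with 10 higher, 11 lower and 16 not called (11 and 13 adjusted over the list alone, adjusted p = 0.853). Their median was 0.02 while the test leaned downwards. The cyclin CCNA2 fell by 0.98 on the log2 scale (SE 0.14, adjusted p = 1.9e-06) and the securin gene PTTG1 rose by 0.78 (SE 0.12, adjusted p = 3.37e-06).

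DNMT1, on chromosome 19 from 10133345 to 10231286 (minus strand, GRCh38), fell from 407 ± 15.6 to 178 ± 14.8 CPM at 24 h (SD, n = 4 each). Its log2 fold change was −1.19 (SE 0.11, adjusted p = 1.01e-10), with all 4 GlyCl libraries below all 4 controls. UHRF1, which recruits DNMT1 to replicated DNA, fell by 1.44 on the log2 scale (SE 0.13, adjusted p = 1.72e-10). AHCY, which clears the methylation by-product S-adenosylhomocysteine, fell by 1.12 (SE 0.13, adjusted p = 2.25e-08). In the DNA methylation and methyl donor list 9 of 21 genes fell, 1 rose and 11 were not called (11 and 1 adjusted over the list alone). The median was −0.21 (camera adjusted p = 0.00526, and adjusted p = 0.189 with an estimated correlation). Under library totals the median was 0.22, with 13 higher and 3 lower, and the list was not called (adjusted p = 0.304). The 1 gene that rose, chosen here after its values were seen, was MAT2A, the enzyme that makes S-adenosylmethionine. It stood at 1120 ± 121 against 249 ± 11.5 CPM (SD, n = 4 each), a log2 fold change of 2.17 (SE 0.37, adjusted p = 0.000131).

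**Figure D1:**
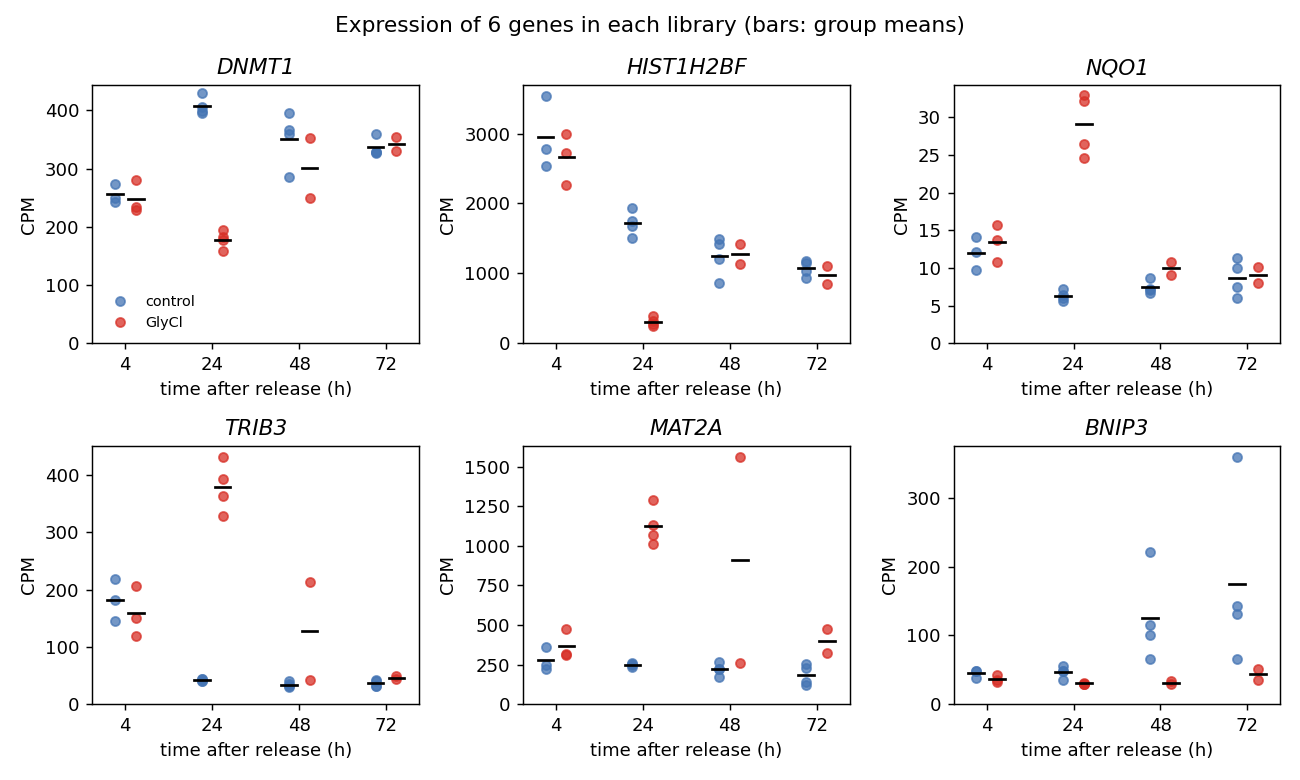
Expression in CPM (linear axis from 0) of DNMT1, HIST1H2BF, NQO1, TRIB3, MAT2A and BNIP3 in each library against hours after release, with control and GlyCl libraries as separate points and black bars at the group means. At 24 h the 4 GlyCl libraries lie below the controls for DNMT1 and HIST1H2BF and above them for NQO1, TRIB3 and MAT2A, and at 48 h the 2 GlyCl libraries differ for TRIB3 (42.8 and 213 CPM) and MAT2A (260 and 1560 CPM).

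Lipid, chaperone and growth genes were low at 24 h as well. All 26 cholesterol and lipid synthesis genes fell (26 adjusted over the list alone), with a median of −1.17 (camera adjusted p = 8.94e-21, and adjusted p = 0.0936 with an estimated correlation). The master regulator SREBF2 fell by 1.56 on the log2 scale (SE 0.12, adjusted p = 1.59e-12) and the desaturase FADS2 by 2.13 (SE 0.16, adjusted p = 4.68e-12). Of 18 heat shock chaperones 17 fell and 1 rose (17 and 1 adjusted over the list alone, camera adjusted p = 1.31e-07, and adjusted p = 0.189 with an estimated correlation). Mitochondrial HSPD1 was among them (−1.17, SE 0.16, adjusted p = 3.61e-07). Of 29 ribosome biogenesis genes 28 fell and 0 rose (28 and 0 adjusted over the list alone, camera adjusted p = 3.8e-13, and adjusted p = 0.189 with an estimated correlation). The nucleolar protein NPM1 fell from 1300 ± 104 to 522 ± 56.9 CPM (SD, n = 4 each, adjusted p = 1.1e-09). Proteasome genes had 30 of 32 lower (30 adjusted over the list alone, camera adjusted p = 2.23e-14) and oxidative phosphorylation genes 31 of 36 (31 adjusted over the list alone, camera adjusted p = 8.63e-11). Both had 0 higher and an adjusted p = 0.189 with an estimated correlation. Ribosomal protein genes had 56 of 75 lower and 0 higher (61 and 1 adjusted over the list alone, camera adjusted p = 3.75e-13, and adjusted p = 0.269 with an estimated correlation). The ribosomal protein median was −0.51, and −0.07 under library totals with 15 lower and 5 higher. Glycolysis and hypoxia genes had 13 lower and 4 higher of 30 (13 and 4 adjusted over the list alone, camera adjusted p = 0.00526, and adjusted p = 0.687 with an estimated correlation). Their median was −0.55, and −0.11 under library totals with 11 lower and 8 higher.

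Stress and signalling genes were among those higher with GlyCl than in controls at 24 h. In the comparisons of GlyCl with control, rose and fell mean against controls of the same hour. In controls the ATF4 list had itself fallen from 4 to 24 h (median −1.36), as had immediate early genes (−1.1). A higher level than controls at 24 h need therefore not be a rise from 4 h. Of 24 ATF4 targets, which respond to amino acid and redox stress, 14 rose, 1 fell and 9 were not called (15 and 1 adjusted over the list alone). Their median was 0.68 (camera adjusted p = 9.46e-05, and adjusted p = 0.351 with an estimated correlation). The pseudokinase TRIB3 rose from 42.3 ± 2.14 to 379 ± 43.5 CPM (SD, n = 4 each, adjusted p = 3.01e-07). The transcription factor CEBPB rose by 1.59 (SE 0.2, adjusted p = 8.44e-07) and PPP1R15A by 1.5 (SE 0.15, adjusted p = 9.14e-10). Of 27 immediate early genes 16 rose and 3 fell (16 and 3 adjusted over the list alone, camera adjusted p = 9.46e-05, and adjusted p = 0.189 with an estimated correlation), FOS by 2.48 (SE 0.29). Among NRF2 targets the quinone reductase NQO1 rose from 6.32 ± 0.635 to 29 ± 4.1 CPM (SD, n = 4 each, adjusted p = 8.17e-13). Thioredoxin, TXN, fell by 0.89 on the log2 scale (SE 0.12, adjusted p = 2.08e-07) and the transketolase TKT by 1.04 (SE 0.14, adjusted p = 1.73e-07). The NRF2 list had 4 higher and 6 lower of 15 (4 and 7 adjusted over the list alone, adjusted p = 0.282). Its median was −0.22, and 0.21 under library totals with 6 higher and 3 lower, while its mean was 0.1 and its test leaned downwards. Thiol redox systems had 15 lower and 1 higher of 26 (17 and 1 adjusted over the list alone, camera adjusted p = 1.8e-05, and adjusted p = 0.189 with an estimated correlation). Both PRDX4 (−1.08, SE 0.12) and SOD1 (−0.96, SE 0.12) were lower. TXNRD1 was not called (−0.29, SE 0.12, adjusted p = 0.0591). It was called with the replicate block (0.0413), with limma-voom (0.046) and with only the 24 h groups in the fit (0.0069).

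Several gene groups that are low or silent in control cells were higher at 24 h. Of 15 tested cancer-testis and germline genes, which DNA methylation keeps silent in most adult cells, 12 rose, 0 fell and 3 were not called (12 and 0 adjusted over the list alone). The median was 2.09 (camera adjusted p = 1.8e-06, and adjusted p = 0.0436 with an estimated correlation). MAGEA4 reached 2.12 ± 0.605 CPM against 0.196 ± 0.105 CPM, and SSX2 2.27 ± 0.231 against 0.0637 ± 0.0256 CPM (SD, n = 4 each). SSX2 and its copy SSX2B cannot be told apart. Of 19 imprinted genes 9 rose and 2 fell (10 and 2 adjusted over the list alone), GRB10 by 2.02 (SE 0.3). That list had a median of 0.56 (camera adjusted p = 0.0298, 0.0513 under library totals, and adjusted p = 0.104 with an estimated correlation). Markers of other cell types moved with them. Of 5 epithelial, fibroblast and endothelial genes 4 rose (4 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.0156, and adjusted p = 0.189 with an estimated correlation). Levels were low, at 1.38 ± 0.548 CPM for VWF and 0.657 ± 0.209 CPM for KRT8, against 0.064 ± 0.0748 and 0.0401 ± 0.0311 CPM in controls (SD, n = 4 each). B cell and myeloid markers had 1 of 8 higher (0 adjusted over the list alone, adjusted p = 0.118). Under library totals 6 of these were higher and 0 lower, with a median of 1.12 in place of 0.69, and 14 imprinted and 8 RNA quality genes were higher with 0 lower. The share of counts in non-coding genes was 2.43 ± 0.379 % with GlyCl and 1.35 ± 0.0616 % in controls (SD, n = 4 each). Of 11 RNA quality genes 5 were higher (5 adjusted over the list alone, adjusted p = 0.0576), RNU1-1 by 1.02. The list passed without control 24 h replicate 3 (0.0394) or GlyCl 24 h replicate 3 (0.021). MALAT1 was higher too (0.81, SE 0.26, adjusted p = 0.0168), a call lost without GlyCl 24 h replicate 1 (0.63, adjusted p = 0.0577).

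Among the largest single increases over controls at 24 h was KLHDC7B, at 8.74 ± 2.05 against 0.261 ± 0.21 CPM (SD, n = 4 each, adjusted p = 2.24e-08). Its level in controls was higher at 4 h than at 24 h, as given below, so this need not be a rise from 4 h. The interleukin-31 receptor gene IL31RA reached 8.29 ± 1.98 against 0.393 ± 0.167 CPM, and the reductase DHRS2 7.8 ± 3.86 against 0.393 ± 0.0876 CPM (SD, n = 4 each). T cell identity genes went both ways, with 10 higher and 13 lower of 30 (11 and 14 adjusted over the list alone, adjusted p = 0.282). Their median was −0.17, and 0.26 under library totals with 15 higher and 6 lower. The recombinase RAG1 fell from 46.8 ± 8.11 to 16.7 ± 3.53 CPM and CD7 by 1.19 on the log2 scale (SE 0.13), while PTPRC rose by 0.76 (SE 0.11). Interferon-stimulated genes were split too, with 8 higher and 8 lower of 28 (8 and 10 adjusted over the list alone, adjusted p = 0.644). IRF7 stood at 1.39 (SE 0.17) and HERC5 at −1.28 (SE 0.11). The interferon median was −0.16, or 0.28 under library totals with 12 higher and 4 lower, with a mean of 0.1 and a test leaning downwards. The p53 response had 8 higher and 6 lower of 23 (8 and 6 adjusted over the list alone, adjusted p = 0.374, and 0.0225 under library totals). The pro-apoptotic BBC3 rose by 1.91 (SE 0.31, adjusted p = 2.28e-05), GADD45B by 1.44 (SE 0.2) and CDKN1A by 0.82 (SE 0.24, adjusted p = 0.00657), while DDB2 fell by 0.81 on the log2 scale (SE 0.12). T cell activation genes had 5 higher and 1 lower (5 and 1 adjusted over the list alone, adjusted p = 0.282), and NF-kappaB targets 5 and 3 (5 and 3 adjusted over the list alone, adjusted p = 0.374). Under library totals 16 NF-kappaB targets were higher and 0 lower, with a median of 0.59 in place of 0.16. Endoplasmic reticulum chaperones had 5 higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.644). Their median was −0.02, and 0.42 under library totals with 8 higher and 0 lower, while the test leaned upwards. Apoptosis genes had 4 higher and 7 lower (5 and 7 adjusted over the list alone, adjusted p = 0.909), with a median of 0.03 and a test leaning downwards. Under library totals 14 apoptosis genes were higher and 1 lower, with a median of 0.46. The mitochondrial genome had 1 higher and 3 lower (0 and 0 adjusted over the list alone, adjusted p = 0.543), with a median of −0.1, and 0.34 under library totals with 1 higher and 0 lower. Metallothioneins had 1 higher (1 adjusted over the list alone, adjusted p = 0.644), and 3 under library totals. MT2A was not called (−0.22, SE 0.25, adjusted p = 0.525). MSRB1 was not called (−0.04, SE 0.12, adjusted p = 0.815), but had 0.39 and adjusted p = 0.00279 under library totals.

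HSPA1A was lower at 24 h, at 1.07 ± 0.405 against 2.34 ± 0.805 CPM (SD, n = 4 each, adjusted p = 0.0307). That call was lost without GlyCl 24 h replicate 1 (adjusted p = 0.0601), replicate 2 (0.0735) or replicate 3 (0.106), and without control 24 h replicate 2 (0.0566) or replicate 4 (0.116). It was also lost under library totals (0.131) and with limma-voom (0.0643). In all, 9095 genes were called at 24 h (39 %), 4190 higher and 4905 lower, of which 2140 and 538 changed at least 2-fold. Long non-coding genes were called higher more often than lower (1139 against 122 of 5232 tested) and protein-coding genes lower more often than higher (4610 against 2557). Their medians were 0.45 and −0.07, so lists of protein-coding genes leaned downwards in the list test here too. Among tested genes with a mean CPM under 1, 84.7 % of protein-coding and 81.3 % of non-coding genes had a higher mean with GlyCl. Weakly expressed genes of both classes thus shared the gain. Library totals move the median log2 fold change of all genes from 0.1 to 0.53, and under them 12694 genes were called, 11236 higher and 1458 lower (88.5 % higher against 46.1 %). By list, library totals left 11 heat shock, 18 ribosome biogenesis, 20 proteasome, 11 oxidative phosphorylation and 9 thiol redox genes called lower. In the same lists 1, 1, 1, 5 and 6 were called higher, and 17 p53 response and 22 G2/M genes were higher with 1 and 2 lower.

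At 48 h the 2 GlyCl libraries differed from one another, and the genes given first here were called whichever single library was left out. KRT1, a keratin, stood at 37.7 and 61.4 CPM in the GlyCl libraries against 6.64 to 13.1 CPM in 4 controls (2.31, SE 0.24, adjusted p = 6.6e-06). CARD6, a caspase recruitment domain gene, rose by 2.95 (SE 0.35, adjusted p = 4.67e-06) and TRIM22, an interferon-inducible gene, by 1.96 (SE 0.25, adjusted p = 6.88e-06). RAG1 was lower, at 26.5 and 14.5 CPM against 56 to 73.6 CPM (−1.71, SE 0.23, adjusted p = 9.11e-05).

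Of the 24 ATF4 targets 14 were higher and 0 lower at 48 h (19 and 0 adjusted over the list alone), with a median of 0.8. The list passed the test (camera adjusted p = 6.9e-11, and adjusted p = 0.385 with an estimated correlation), but not without GlyCl 48 h replicate 2 (adjusted p = 0.559). TRIB3 stood at 42.8 CPM in GlyCl replicate 1 and 213 CPM in replicate 2, against 30.3 to 39.7 CPM in controls (1.91, SE 0.35, adjusted p = 0.00462). Without replicate 2 its log2 fold change was 0.33 (adjusted p = 0.861). For MAT2A the values were 260 and 1560 CPM against 173 to 266 CPM (2.05, SE 0.42, adjusted p = 0.00992), and 0.24 without replicate 2 (adjusted p = 0.953). The glutathione-degrading enzyme CHAC1 rose by 2.39 (SE 0.42, adjusted p = 0.00308) and the cell cycle inhibitor CDKN1A by 1.72 (SE 0.29, adjusted p = 5e-04). Without replicate 2 these were 0.65 (adjusted p = 0.808) and 1.47 (adjusted p = 0.146). A fit of only the 48 h groups also ended the calls of TRIB3 (adjusted p = 0.433), MAT2A (0.429), CHAC1 (0.367) and CDKN1A (0.0778), and limma-voom that of MAT2A (0.0855). With only the shared replicate numbers and the replicate block, TRIB3 (0.0594) and MAT2A (0.0527) were not called.

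Some lists were called at 48 h with any single library left out. Of 37 G2/M genes 3 fell (18 adjusted over the list alone), with a median of −0.4 (camera adjusted p = 5.9e-12). Of 30 glycolysis and hypoxia genes 2 fell (6 adjusted over the list alone), with a median of −0.54 (camera adjusted p = 6.05e-10). Of 27 immediate early genes 6 rose (11 adjusted over the list alone), with a median of 0.51 (camera adjusted p = 1.41e-08). All 3 lists had an adjusted p = 0.385 with an estimated correlation. Of 75 ribosomal protein genes 1 fell (0 adjusted over the list alone), with a median of −0.21 (camera adjusted p = 1.8e-05, and adjusted p = 0.602 with an estimated correlation). The hypoxia-induced mitophagy gene BNIP3 stood at 33.4 and 29.2 CPM against 66.3 to 221 CPM (−2.01, SE 0.52, adjusted p = 0.0416). That call was lost without GlyCl 48 h replicate 1 (0.114), GlyCl replicate 2 (0.64), control replicate 1 (0.105) or control replicate 4 (0.0632). It was also lost with limma-voom (0.0523) or only the 48 h groups (0.329).

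G1/S genes were not called at 48 h, with 2 higher and 0 lower of 31 (3 and 0 adjusted over the list alone, camera adjusted p = 0.0948). The G1/S list passed upwards without control 48 h replicate 1 (0.0148) or control 48 h replicate 2 (0.017) and under library totals (0.0443). Most other 48 h list calls were lost or reversed without GlyCl 48 h replicate 2, while those of interferon-stimulated genes and histones were kept. Cholesterol synthesis had 0 of 26 called and 8 lower adjusted over the list alone (camera adjusted p = 7.81e-08, 0.794 without that library, and adjusted p = 0.385 with an estimated correlation). NF-kappaB targets had 4 higher, and 7 higher and 1 lower adjusted over the list alone (0.00264, 0.379 without it, and adjusted p = 0.385 with an estimated correlation). Heat shock chaperones had 1 lower, also adjusted over the list alone (0.000746, 0.628 without it, and adjusted p = 0.494 with an estimated correlation). Oxidative phosphorylation had 0 called, also adjusted over the list alone (0.000481, 0.574 without it, and adjusted p = 0.494 with an estimated correlation), and was lost without control 48 h replicate 2 (0.0532). Apoptosis genes had 2 higher, 4 adjusted over the list alone (0.0201, 0.154 without it, and adjusted p = 0.385 with an estimated correlation), and were lost without control 48 h replicate 3 (0.0549). The p53 list had 4 higher, and 6 higher and 2 lower adjusted over the list alone (adjusted p = 0.017, and adjusted p = 0.385 with an estimated correlation). It was lost without GlyCl 48 h replicate 2 (0.17), without control 48 h replicate 3 (0.0717) and with the replicate block (0.0834). The RNA quality list had 2 higher, 3 adjusted over the list alone (adjusted p = 0.0306, and adjusted p = 0.494 with an estimated correlation). It was lost without GlyCl 48 h replicate 2 (0.377), control replicate 1 (0.0529) or control replicate 2 (0.126), and with the block (0.099). Interferon-stimulated genes had 4 higher, and 6 higher and 1 lower adjusted over the list alone (adjusted p = 0.00264, 0.0585 without control 48 h replicate 3, and adjusted p = 0.385 with an estimated correlation). Histones had 1 higher, also adjusted over the list alone (adjusted p = 0.021, and adjusted p = 0.771 with an estimated correlation). They were lost without GlyCl replicate 1 (0.765), control replicate 1 (0.0529) or control replicate 3 (0.751), and with the block (0.148). The proteasome list, with 0 called also adjusted over the list alone, passed downwards (adjusted p = 0.0115, and adjusted p = 0.759 with an estimated correlation). It was called upwards without GlyCl 48 h replicate 2 (0.02) and lost without control replicate 2 (0.495) and with the block (0.0591).

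DNMT1 was not called at 48 h, at 301 ± 72.6 CPM (SD, n = 2) against 352 ± 46.4 CPM (SD, n = 4, adjusted p = 0.42). MT2A (0.15, adjusted p = 0.864), TXNRD1 (0.03, adjusted p = 0.95), MSRB1 (0.08, adjusted p = 0.846) and HSPA1A (−0.22, adjusted p = 0.871) were not called. In all, 757 genes were called at 48 h, 561 higher and 196 lower (3.24 %), and 1145 with the replicate block, 741 higher and 404 lower. Without GlyCl 48 h replicate 2 the count was 20, without GlyCl 48 h replicate 1 it was 1265, and without control 48 h replicate 1 it was 458. Only the 48 h groups gave 96.

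At 72 h few genes differed. The liver-type methionine adenosyltransferase MAT1A stood at 12.1 ± 1.82 CPM (SD, n = 2) against 5.43 ± 0.612 CPM (SD, n = 4, adjusted p = 0.00339). LSAMP, a cell adhesion gene known from neurons, stood at 15.8 ± 0.213 CPM (SD, n = 2) against 37.6 ± 5.06 CPM (SD, n = 4, adjusted p = 0.0211). The other 2 called genes were CCNI2, a cyclin-family gene (0.97, SE 0.18, adjusted p = 0.0343), and LINC01891 (−2.64, SE 0.5, adjusted p = 0.0343). Without GlyCl 72 h replicate 1 all 4 calls were lost (adjusted p = 0.607 for MAT1A and LSAMP, 0.647 for CCNI2 and 0.663 for LINC01891). Without GlyCl 72 h replicate 3 those of LSAMP, CCNI2 and LINC01891 were lost (0.727 each). Without control 72 h replicate 1 the same 3 genes had 0.0845, 0.185 and 0.223, and without control 72 h replicate 2 0.0629, 0.211 and 0.147. Only the 72 h groups in the fit ended the calls of MAT1A (0.0654), CCNI2 (0.348) and LINC01891 (0.386), only the shared replicate numbers that of CCNI2 (0.0649), and limma-voom that of LINC01891 (0.155). DNMT1 stood at 342 ± 17 CPM (SD, n = 2) and 336 ± 15.8 CPM (SD, n = 4, adjusted p = 0.974). CDKN1A (0.5, adjusted p = 0.58), TXNRD1 (0.28, adjusted p = 0.521), MT2A (−0.19, adjusted p = 0.88), MSRB1 (0.25, adjusted p = 0.553) and HSPA1A (0.26, adjusted p = 0.895) were not called.

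As a group, glycolysis and hypoxia genes were lower at 72 h, with 0 of 30 called over all genes and 19 lower adjusted over the list alone. Their median was −0.71 (camera adjusted p = 2.27e-16, and adjusted p = 0.628 with an estimated correlation). Such genes varied widely between controls at 72 h, with BNIP3 at 175 ± 128 CPM and HK2 at 171 ± 101 CPM (SD, n = 4). Single members were not called, such as the glycolytic enzymes ENO1 (−0.6, adjusted p = 0.486) and GAPDH (−0.26, adjusted p = 0.604). Ribosome biogenesis genes were higher as a group, with 0 called, 6 higher adjusted over the list alone and a median of 0.32 (camera adjusted p = 2.04e-12, and adjusted p = 0.628 with an estimated correlation). Endoplasmic reticulum chaperones also passed upwards, with 0 called and 2 higher adjusted over the list alone (0.000202, and adjusted p = 0.628 with an estimated correlation). ATF4 targets did so with 0 called, 4 higher and 1 lower adjusted over the list alone (0.00051, and adjusted p = 0.702 with an estimated correlation), and the proteasome with 0 called, also adjusted over the list alone (0.000263, and adjusted p = 0.702 with an estimated correlation). G1/S genes (0.00179) and heat shock chaperones (0.00335) passed upwards with 0 called, also adjusted over the list alone, but not without GlyCl 72 h replicate 1 (0.586 and 0.0923). Both had an adjusted p = 0.702 with an estimated correlation. Apoptosis genes passed upwards with 0 called and 1 higher adjusted over the list alone (0.0383, and adjusted p = 0.628 with an estimated correlation). That call was lost without GlyCl 72 h replicate 1 (0.348), control 72 h replicate 1 (0.0716) or control 72 h replicate 2 (0.0672), and under library totals (0.0671). Cholesterol synthesis passed downwards with 0 called, also adjusted over the list alone (0.00666, 0.258 without GlyCl 72 h replicate 3, and adjusted p = 0.745 with an estimated correlation). NRF2 targets were not called (0 of 15, also adjusted over the list alone, adjusted p = 0.0981), but were with the replicate block (0.013) and without control 72 h replicate 4 (0.0471). G2/M and T cell identity genes were not called either (camera adjusted p = 0.0981 each). They passed downwards without control 72 h replicate 3 (0.0347 and 0.0363) and under library totals (0.0395 and 0.0388).

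In all, 4 genes were called at 72 h, 2 higher and 2 lower, while 2439 had an unadjusted p under 0.05. The DESeq2 Wald test called 95, 21 higher and 74 lower, and the replicate block gave 73, 37 higher and 36 lower. Only the shared replicate numbers gave 67, of which 59 were lower, and 213 with the block. Library totals gave 10, of which 8 were lower, and only the 72 h groups gave 1. Leaving out control 72 h replicate 4 gave 357 and control 72 h replicate 3 gave 17. Leaving out GlyCl 72 h replicate 1 gave 0, and leaving out control 72 h replicate 1, control 72 h replicate 2 or GlyCl 72 h replicate 3 gave 1 each.

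**Figure D2:**
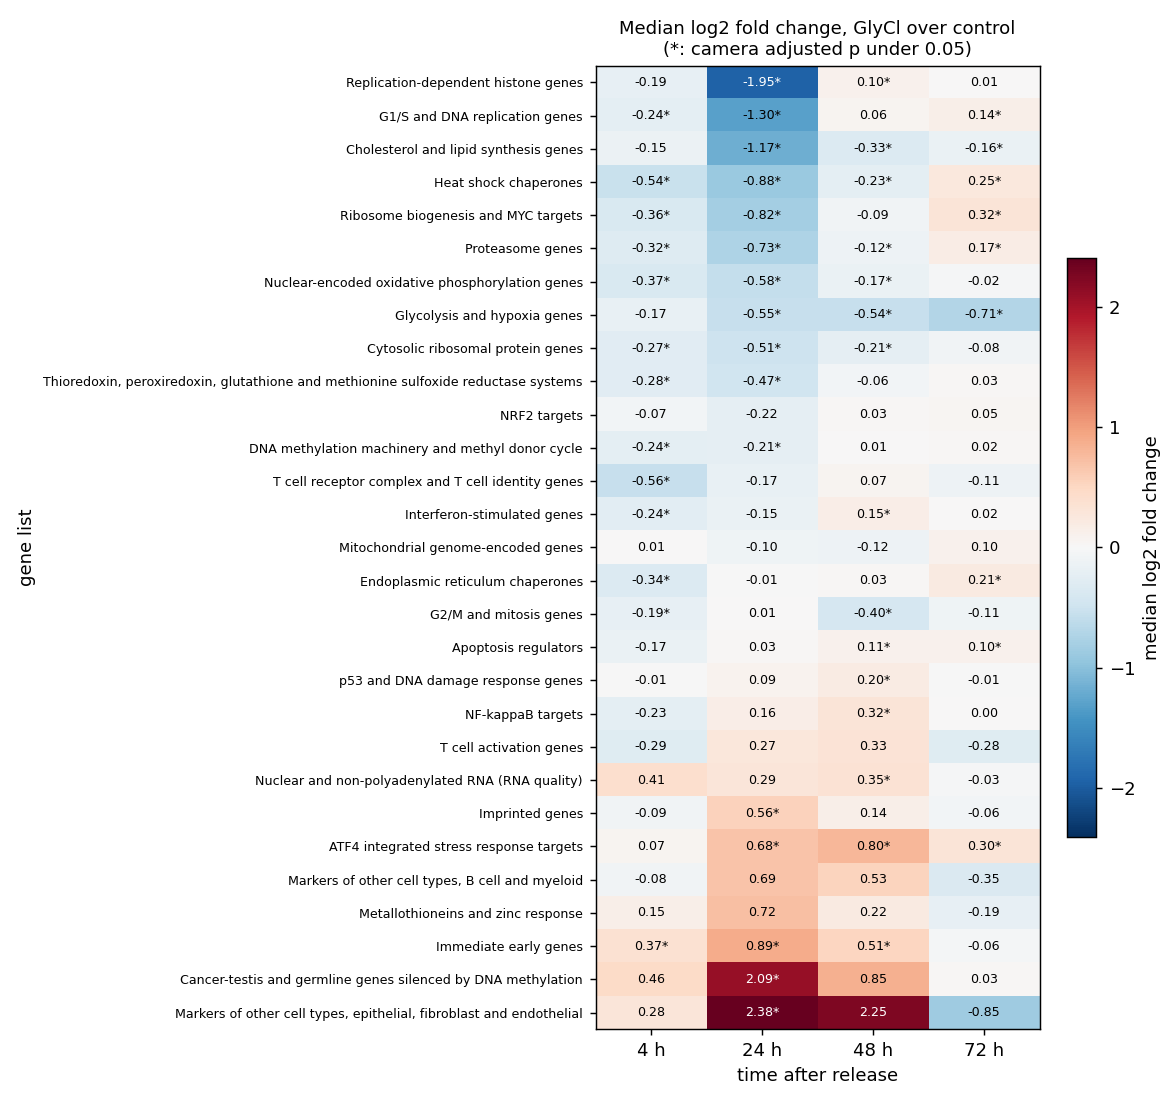
Median log2 fold change, GlyCl against control, of each of the 29 gene lists (vertical axis) at 4, 24, 48 and 72 h (horizontal axis), as colour, with an asterisk where the camera adjusted p is under 0.05 at the preset correlation. At 24 h histone (−1.95), G1/S (−1.3) and cholesterol (−1.17) genes are low and cancer-testis genes (2.09) high, and under library totals the DNA methylation list at 24 h has a median of 0.22 in place of −0.21 and G2/M genes at 4 h 0.02 in place of −0.19.

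The effect of GlyCl itself changed with time, by a test of the difference between effects. The effect on KLHDC7B, a gene of the kelch domain family, changed by 5.76 on the log2 scale from 4 h to 24 h (SE 0.63, adjusted p = 1.21e-06). Its level in controls fell over the same time, as given below. The effect on HIST1H2BF changed by −2.31 (SE 0.23, adjusted p = 2.83e-08), on HIST3H3 by −2.49 (SE 0.35, adjusted p = 1.77e-05) and on DNMT1 by −1.15 (SE 0.16, adjusted p = 5.59e-06). From 4 h to 48 h the effect on CDHR5, a cadherin family gene, changed by −2.39 (SE 0.43, adjusted p = 0.000523). From 4 h to 72 h it changed by 1.79 for HSPA8 (SE 0.27, adjusted p = 2e-04), by 1.87 for APOL1 (SE 0.3, adjusted p = 0.000351) and by −2.97 for HIST3H3 (SE 0.45, adjusted p = 0.000499). From 4 h to 24 h 3406 genes changed in effect, 1926 upwards and 1480 downwards, and under library totals 4408, 3674 upwards and 734 downwards. A fit of only the groups compared gave 4599, with 2115 upwards and 2484 downwards. More went downwards also without GlyCl 24 h replicate 2 (1430 against 1280), replicate 3 (1724 against 1436) or replicate 4 (1486 against 1325).

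From 4 h to 48 h 1617 genes changed in effect, 1252 upwards and 365 downwards, and under library totals 1052 (521 and 531). Single libraries moved that count to 905 without GlyCl 4 h replicate 1, 528 without GlyCl 48 h replicate 2 and 2623 without control 48 h replicate 2. Only the groups compared gave 624, and only the shared replicate numbers 777. From 4 h to 72 h 1684 changed, 1311 upwards and 373 downwards, and 2637 with the replicate block (2001 and 636). Under library totals the count was 791 (212 and 579). It was 589 without GlyCl 4 h replicate 1, 210 without GlyCl 72 h replicate 1 and 613 without GlyCl 72 h replicate 3. It was 977 without control 4 h replicate 2, 912 without control 4 h replicate 3, 1074 without control 72 h replicate 1 and 769 without control 72 h replicate 2.

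Control cells themselves changed between 4 h and later times, which gives the background of every comparison above. At 24 h against 4 h HSPA8 rose from 480 ± 113 CPM (SD, n = 3) to 3430 ± 205 CPM (SD, n = 4, adjusted p = 2.9e-12). MYC, a driver of cell growth, rose from 86.9 ± 21.8 CPM (SD, n = 3) to 345 ± 36.4 CPM (SD, n = 4, adjusted p = 4.26e-09). The cystine transporter SLC7A11 fell from 199 ± 24.8 CPM (SD, n = 3) to 10.6 ± 1.15 CPM (SD, n = 4, adjusted p = 2.85e-07). The stress gene SESN2 fell by 2.89 on the log2 scale (SE 0.23) and CDKN1A by 2.82 (SE 0.24, adjusted p = 7.84e-11). KLHDC7B went from 11.8 ± 1.04 CPM (SD, n = 3) to 0.261 ± 0.21 CPM (SD, n = 4). DNMT1 rose from 256 ± 16.4 CPM (SD, n = 3) to 407 ± 15.6 CPM (SD, n = 4, adjusted p = 2.63e-05).

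By list, 28 of 29 ribosome biogenesis genes rose in controls from 4 to 24 h (28 adjusted over the list alone), with a median of 0.97 (camera adjusted p = 1.05e-16, and adjusted p = 0.125 with an estimated correlation). Heat shock chaperones rose too, 16 of 18 (16 adjusted over the list alone, camera adjusted p = 4.76e-13, and adjusted p = 0.125 with an estimated correlation). The proteasome had 25 of 32 higher (29 adjusted over the list alone, camera adjusted p = 4.3e-09, and adjusted p = 0.347 with an estimated correlation). Histones fell, 49 of 55 (50 adjusted over the list alone, camera adjusted p = 5.57e-16, and adjusted p = 0.223 with an estimated correlation). ATF4 targets fell, 19 of 24 (19 adjusted over the list alone), with a median of −1.36 (camera adjusted p = 1.01e-11, and adjusted p = 0.133 with an estimated correlation). The p53 response had 16 of 23 lower (16 lower and 1 higher adjusted over the list alone, camera adjusted p = 3.6e-07, and adjusted p = 0.0678 with an estimated correlation). Immediate early genes had 16 lower and 1 higher of 27 (19 and 2 adjusted over the list alone, camera adjusted p = 2.88e-07, and adjusted p = 0.125 with an estimated correlation). T cell activation genes had 6 lower and 1 higher of 12 (8 and 1 adjusted over the list alone, camera adjusted p = 0.00574, and adjusted p = 0.0678 with an estimated correlation). Metallothioneins had 4 of 5 lower (4 adjusted over the list alone, camera adjusted p = 0.00917, and adjusted p = 0.125 with an estimated correlation), and MT1E fell by 3.33 on the log2 scale (SE 0.48). Ribosomal proteins had 7 of 75 higher (5 adjusted over the list alone, adjusted p = 0.0395, and adjusted p = 0.751 with an estimated correlation). That call was lost with the replicate block (0.0973), DESeq2 size factors (0.0558) and library totals (0.0774). It was also lost without control 24 h replicate 1 (0.0746), control 24 h replicate 4 (0.132) or control 4 h replicate 3 (0.0996). The mitochondrial genome list had 1 of 13 higher (0 adjusted over the list alone, adjusted p = 0.0415, and adjusted p = 0.655 with an estimated correlation). It was lost with the block (0.0545), under library totals (0.0521) or without control 24 h replicate 1 (0.0754), control 24 h replicate 2 (0.0928) or control 4 h replicate 2 (0.145).

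Many of these lists were also called in controls at 48 and 72 h against 4 h. Histones had 53 of 55 genes lower at both times (53 adjusted over the list alone), with medians of −1.17 and −1.41. Their camera adjusted p was 1.68e-26 and 4.29e-34, with adjusted p = 0.121 and 0.115 with an estimated correlation. HIST1H4I went from 2600 ± 413 CPM at 4 h (SD, n = 3) to 957 ± 95.4 and 750 ± 22.6 CPM (SD, n = 4 each). ATF4 targets had 19 of 24 lower at both times (19 adjusted over the list alone, camera adjusted p = 1.51e-10 and 2.19e-10, and adjusted p = 0.151 and 0.196 with an estimated correlation). Ribosomal proteins were higher at 72 h, 39 of 75 (47 adjusted over the list alone, camera adjusted p = 2.79e-09, and adjusted p = 0.475 with an estimated correlation). Hypoxia-linked genes varied between controls at 72 h. BNIP3 was at 175 ± 128 CPM (SD, n = 4) against 45 ± 6.08 CPM (SD, n = 3) at 4 h (adjusted p = 0.002, and 0.0701 with only these groups in the fit). The hexokinase HK2 was at 171 ± 101 CPM (SD, n = 4) against 48.7 ± 10.2 CPM (SD, n = 3, adjusted p = 0.000306). DNMT1 stayed above its 4 h level at 48 h (0.46, SE 0.12, adjusted p = 0.00211) and at 72 h (0.4, SE 0.12, adjusted p = 0.00812). The latter was lost without control 4 h replicate 3 (0.33, adjusted p = 0.0642). In all, 7633 genes were called at 24 h (3610 higher, 4023 lower), 7726 at 48 h (3799 and 3927) and 7329 at 72 h (3672 and 3657).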

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

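The 2 tests of gain per kb of exon were added after the first test for genomic DNA had left it undecided, with bounds written before their own results, while the tests at 4 h, the comparisons by gene length and the reason for not relying on these tests were chosen after the result was seen. In 12 of 211 group and measure pairs tested, 1 library lay far from the other 3 of its group by Dixon's ratio, which chance gives in about 1 of 20. The share of counts in non-coding genes was 1.26 % in control 24 h replicate 2 and 2.99 % in GlyCl 24 h replicate 1. GlyCl 24 h replicate 1 also stood apart for HIST1H2AH (156 CPM) and MALAT1 (8730 CPM). Control 24 h replicate 2 stood apart for KLHDC7B (0.574 CPM), control 24 h replicate 3 for PPP1R15A (13 CPM), FADS2 (551 CPM) and CHORDC1 (110 CPM), and control 24 h replicate 4 for MSRB1 (18.8 CPM). Among later controls, TNF stood apart in 48 h replicate 1 (0.042 CPM), MT2A in 48 h replicate 4 (26.9 CPM) and DNMT1 in 72 h replicate 1 (360 CPM).

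The GlyCl effect differed between times by a test of the difference for 3406 genes between 4 and 24 h, 1617 between 4 and 48 h and 1684 between 4 and 72 h. From 4 to 24 h the effect on KLHDC7B changed by 5.76 on the log2 scale, on HIST3H3 by −2.49, on HIST1H2BF by −2.31 and on DNMT1 by −1.15. HIST3H3 stood at 2.23 CPM with GlyCl and 2.52 CPM in controls at 24 h and was not called there (adjusted p = 0.67), but it was called higher again at 48 h (2.25, adjusted p = 8.26e-05), a call lost without GlyCl 48 h replicate 2 (1.73, adjusted p = 0.0617). From 4 to 48 h the changes were 3.83 for IL31RA, 3.48 for RGS16, −2.59 for ALPK3, −2.39 for CDHR5 and 1.37 for CDKN1A. Without GlyCl 48 h replicate 2 those of IL31RA (1.16, adjusted p = 0.388), RGS16 (0.77, adjusted p = 0.545), ALPK3 (−2.31, adjusted p = 0.079) and CDKN1A (1.11, adjusted p = 0.166) were not called. That of CDKN1A was also lost without GlyCl 4 h replicate 1 (1.26, adjusted p = 0.062), under library totals (0.0601) and with only the shared replicate numbers (0.0799), and that of RGS16 with the shared numbers and the replicate block (0.0505). From 4 to 72 h they were 1.79 for HSPA8, 1.87 for APOL1, −2.97 for HIST3H3 and −4.4 for MIR210HG. The call of MIR210HG was lost without control 4 h replicate 1 (adjusted p = 0.0603), replicate 2 (0.073) or replicate 3 (0.0764), and without GlyCl 4 h replicate 1 (0.109) or replicate 2 (0.0584). It was also lost without control 72 h replicate 1 (0.0533) or replicate 2 (0.0707), without GlyCl 72 h replicate 1 (0.167) or replicate 3 (0.133), with limma-voom (0.196) and with only the groups compared (0.111). In the fit of only the 4 and 24 h groups, 3 of 100 splits of these libraries, the real one included, changed as many genes in effect, with 4599 for the real split and 5919 for the highest other. Of the 9 splits that part all 7 same-numbered pairs, 3 came as high, and the highest of the rest gave 3966. The 2 others that came as high keep the real arms of all 8 libraries at 24 h and change those of 4 of the 6 at 4 h, so the count follows the 24 h effect and does not exclude chance for the change of effect.

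The share of counts in non-coding genes was higher with GlyCl at 4 h (1.87 against 1.4 %) and at 24 h (2.43 against 1.35 %). A mere loss of counts from histones and other abundant genes is argued against by the medians after TMM scaling. The median log2 fold change of non-coding genes exceeded that of protein-coding genes by 0.46 at 4 h (95 % interval 0.44 to 0.48). At 24 h it did so by 0.52 (0.49 to 0.54). The intervals in this paragraph come from resampling genes, which are not independent. They do not measure the spread between libraries. The classes were not matched for expression in this difference. Among genes with a mean CPM under 1, 84.7 % of protein-coding and 81.3 % of non-coding genes were higher at 24 h. Transcription running past gene ends is argued against at 24 h. Non-coding genes just downstream of expressed genes on the same strand gained less than those just upstream (difference −0.18, interval −0.39 to −0.03). That value leaves genomic DNA in the RNA undecided. Whether strand was kept is not given, so reads past the ends of opposite-strand genes could add to either set. Non-coding genes with no expressed gene within 10000 bp on either strand had a median of 0.56, against 0.31 downstream and 0.49 upstream. At 4 h transcription past gene ends stays open (0.03, −0.09 to 0.14). At 24 h the gain per kb of exon in weakly expressed genes was 2.82 times as high in non-coding as in protein-coding genes (interval 2.55 to 3.15), past the bound of 2 set beforehand against genomic DNA, and 1.97 times (1.83 to 2.11) without the filter on counts used here. The median gain of weakly expressed protein-coding genes was 0.136 CPM at 1 to 2 kb and 0.224 CPM at 4 to 8 kb, and so rose less than length. At equal length the classes lay closer (ratio 1.22 at 1 to 2 kb and 1.12 at 2 to 4 kb). Without that filter the gains were 0.13 against 0.0927 CPM per kb at 1 to 2 kb and 0.0816 against 0.0707 at 2 to 4 kb. The bound of 2 was wrong for this table, which holds 0 genes without counts. Its lowest summed counts per kb are 23.6 at 0.5 to 1 kb and 3.87 at 4 to 8 kb, so short genes with few reads per kb are missing. That lack can also make the gain rise less than length, so the gains by length do not decide on DNA. For low-level genes such as MAGEA4, VWF and KRT8, genomic DNA cannot be told apart from wider transcription of silent genes, which was not tested.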

How the results depend on the processing

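Library totals, the fit without both GlyCl 48 h libraries and the list tests without single libraries were chosen after seeing the data. Over all alternatives, 155 counts of called genes lay within 1.5 times the reported count and 36 did not; for counts of called lists these were 72 and 10. For single genes, 3212 of 3352 refits kept direction and side of the threshold, 135 lost the call, 4 gained one and 1 reversed: MSRB1 at 24 h, 0.39 under library totals. DESeq2 size factors, the DESeq2 Wald test, no filter on low counts and the non-robust fit changed no gene call; a fit of only the groups compared ended 23, limma-voom 9, library totals 8 and single libraries left out 84 of 1387. The replicate block changed the counts of called genes at 48 h to 1145, at 72 h to 73 and of the change from 4 to 72 h to 2637; it added the call of TXNRD1 at 24 h, changed the list calls given for 4, 48 and 72 h and for controls at 24 h, and those of G1/S genes (adjusted p = 0.0571) and B cell and myeloid markers (0.0739) in controls at 48 h, which it ended, and of hypoxia genes in controls at 72 h (0.0194), which it added; among the genes and lists named it changed no other call. Library totals gave 1837 genes at 4 h, 10 at 72 h, and 1052 and 791 changing in effect from 4 h to 48 and 72 h. Only the groups compared gave 96 at 48 h, 1 at 72 h and 624 for the change to 48 h. Only the shared replicate numbers gave 67 at 72 h, 213 with the replicate block, and 777 for the change to 48 h. The DESeq2 Wald test gave 95 at 72 h. Camera with an estimated correlation called 1 list at 24 h, the cancer-testis genes, and 0 at 4, 48 and 72 h and in the control comparisons at 24, 48 and 72 h; fry, which does not compare a list with other genes, called 3 at 48 h and 0 at 72 h. The cause of these moves was not tested, except that fits of fewer libraries have fewer degrees of freedom. Leaving out each library in turn gave 801 to 2660 called genes at 4 h, 7493 to 8674 at 24 h, 20 to 1265 at 48 h and 0 to 357 at 72 h. The counts changing in effect were 2542 to 3264 to 24 h, 528 to 2623 to 48 h and 210 to 2449 to 72 h, and those of controls 6196 to 6831, 6098 to 7807 and 5741 to 6782 at 24, 48 and 72 h against 4 h. Called lists numbered 13 to 15 at 4 h, 16 to 17 at 24 h, 9 to 16 at 48 h and 8 to 11 at 72 h, and 13 to 16, 13 to 16 and 15 to 16 in controls. With 1 GlyCl library left at 48 or 72 h, that library is assumed to vary like the other groups. At these depths, 1.5-fold changes were recovered for 56 % of simulated genes at 4 h, 48 % at 24 h, 32 % at 48 h and 24 % at 72 h. These genes had a mean CPM of at least 1.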

Other observations

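The comparison with matched random lists, the test of r under library totals and the tests for a mislabelled library by genes called with replicate 2 and by genes called for a single library were chosen only after the result they bear on was seen, the bounds of those for a mislabelled library being written before their own values. Further values of control cells at 48 h against 4 h follow. Cholesterol and lipid synthesis genes were higher (13 of 26 higher, 1 lower; 14 and 1 adjusted over the list alone; camera adjusted p = 0.000658, and adjusted p = 0.479 with an estimated correlation), as were oxidative phosphorylation genes (18 of 36 higher; 23 adjusted over the list alone; camera adjusted p = 1.36e-05, and adjusted p = 0.393 with an estimated correlation). T cell activation genes were lower (7 of 12 lower, 1 higher; 8 and 1 adjusted over the list alone; camera adjusted p = 0.00265, and adjusted p = 0.0828 with an estimated correlation).

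At 24 h the medians of 3 lists of weakly expressed genes were set against those of 10000 random lists of protein-coding genes of like expression. The cancer-testis median of 2.09 compares with a random median of 1 (central 95 % from 0.38 to 1.88; 110 as high), the imprinted median of 0.56 with 0.17 (−0.13 to 0.49; 82 as high) and the epithelial, fibroblast and endothelial median of 2.38 with 0.72 (−0.07 to 2.22; 128 as high). Random lists of such genes thus also had positive medians, so part of these increases was shared by weakly expressed genes in general.

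Across genes the GlyCl effect at 24 h tended to run opposite to the change of controls after 4 h, but not in every list: histones fell with GlyCl (median −1.95) and in controls at 24, 48 and 72 h (−0.78, −1.17 and −1.41). Control libraries common to both comparisons are argued against as the cause, since the effect and the change of controls from 4 to 48 h, which share no library, had r = −0.42 across 14950 genes, which are not independent (rho = −0.35; r from −0.46 to −0.36 leaving out 1 control 48 h library). Whether treated cells were only behind on the controls' path was asked over the 2678 genes called with at least a 2-fold change. Of these, 21.2 % lay between the control means at 4 and 48 h and 78.5 % lay beyond both. This goes against a state between those means for most of these genes, which were chosen for a large difference at 24 h. It cannot decide on a delay to a state not sampled in controls, since it takes genes to move steadily between the sampled times. Scaling is argued against by construction, since a factor per library shifts all genes alike and so can neither make nor end this r (−0.42 under library totals, which is fixed and no further test), and the G1/S median (−1.3 under DESeq2 size factors, −0.87 under library totals) does not bear on this pattern, as that list did not rise in controls (−0.12 at 48 h).

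At 48 h GlyCl replicate 1 lay near the controls, and replicate 2 lay further than replicate 1 towards the GlyCl 24 h libraries. Their slopes on the 24 h effect were −0.03 and 0.42, so replicate 2 showed only part of that effect. Single 48 h controls 1 to 4, each against the other 3, had slopes of −0.01, −0.23, 0.23 and 0.01. A late culture of replicate 2 as a whole is argued against, since its control had a slope of −0.23. Whether replicate 1 is a mislabelled control cannot be told apart from a recovered culture, which was not tested: it lay beyond 3 controls in the direction of the 24 h effect for 25.4 % of genes, against 18.4, 15.2, 38.5 and 26.4 % for single controls and 60.5 % for replicate 2. Against a wrong label go the genes called with replicate 2, over which replicate 1 lay beyond 3 controls for 63.7 % (60.2 to 66.5 % over the controls left out), above the 22, 47.1, 51.8 and 31.2 % of left-out controls but not by more than their SD of 13.8. The number of genes called for a single library against 3 controls, assumed to vary like the other groups, was 10, 34, 20 and 5 for replicate 1 (control 1, 2, 3 or 4 left out) and 0, 167, 731 and 0 for controls 1 to 4, and decides little, since controls 2 and 3 stand apart themselves.

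Other divisions of the same libraries were counted in fits of only those libraries without the replicate block. At 24 h 1 of 35 splits, the real one, called as many genes (10139, highest other 1). The same held for controls against 4 h at 24 h (8969 and 1), 48 h (5831 and 1545) and 72 h (6878 and 692). Chance is excluded only if all 35 splits are taken as equally likely, which ignores the replicate numbers. Only 8 of the 35 splits part as many same-numbered pairs as the real one. Among these the highest other was 0 for GlyCl at 24 h and 0, 1 and 692 for controls at 24, 48 and 72 h. The 1545 came from a split that parts fewer. These 8 are too few for a share under 0.05, so with the pairing kept these counts do not exclude chance. At 4 h the 10 splits are too few for a share under 0.05 (1997 genes for the real split, highest other 5, which is among the 4 splits that part all 3 pairs).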
